A study of Williopsis jadinii with 8 samples.

How the data were processed

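Total RNA of 8 yeast cultures was extracted with glass beads and purified on RNeasy columns, and 500 ng of RNA was labelled with Cy3 in a one-colour kit, per the labels' protocols. Precultures ran for 3 days on 20 g/L glucose. The labels give the main glucose medium as 20 g/L glucose and the xylose medium as 50 g/L xylose, each with 10 g/L yeast extract and 20 g/L peptone. The glucose medium's name has the same number as that of the 50 g/L xylose medium, so the stated 20 g/L is uncertain, and whether the amount of sugar also differed between the groups is not settled here. The arrays were read with Agilent Feature Extraction 9.5.3.1, per the file headers and the submitters' processing notes. The deposited scanner files give, per the file headers, the processed signal intensity of each of 15744 spots on a linear scale, background-subtracted but not normalized between arrays, the median spot and local background intensities, and 0 or 1 flags. A deposited value table gives for each spot the ratio of the processed signal to one number per array, as its values show: the quotient of the 2 was constant within each array to 4 digits (2987 for WT glucose replicate 1, for example). It is on a linear scale and not centred by gene, and its column medians are 0.300, 0.293 and 0.291 (WT on glucose), 0.317, 0.307 and 0.316 (WT on xylose) and 0.299 and 0.299 (TMS174). How the authors chose that number is not given in the sources used here; it lies close to the 75th percentile.

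From the deposited signal intensity, the main values were computed as log2 of the processed signal minus the log2 of each array's 75th percentile over the 15208 non-control probes. The 75th percentiles were 2996, 3179 and 2958 intensity units for WT on glucose, 3844, 3962 and 4130 for WT on xylose and 3554 and 3353 for TMS174. The 536 control spots were left out, as were 0 to 10 spots per array that the deposited outlier flags mark. Probes well above background on at least 2 arrays were kept (14195), and the kept probes of a design ID were averaged on the log2 scale, giving 7966 tested design IDs, 6229 of them with 2 probes. The other 638 were not tested. Where both probes of a design ID were called, they went in opposite directions for 27 of 3868 design IDs between the media in WT and for 1 of 587 between the strains. Across design IDs, fold changes of the 2 probes correlated at r = 0.95 and 0.91.

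The design IDs are those of the array. None of the 8604 matched a locus tag or symbol of the 6184 genes in the RefSeq table of the Cybja1 assembly, and their coordinates were not used here. The groups, tests, naming rule, 932 gene symbols in 32 lists and most alternatives had been fixed before the data were examined. Without a match the lists could not be applied, and no gene list was tested. The rule for naming then allowed the 2 probes with the largest rise and the 2 with the largest fall in each of the 2 main comparisons, among probes past an adjusted p of 0.05 whose groups do not overlap; the design IDs of those probes are named. The rule ranks fitted values, so a design ID not above background in 1 group has only a lower bound as its fold. A bound is also given where only part of a group's spots were above background, chosen after seeing the data.

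Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit with group means over all 8 arrays, which share 1 estimate of the spread with 5 residual degrees of freedom, contrasts, eBayes), with two-sided p-values adjusted by the method of Benjamini and Hochberg at 0.05. The p-values measure the spread between these cultures. On simulated arrays with 68, 66 and 66 design IDs changed by 0.5, 1 and 2 on the log2 scale among 7966, the same steps recovered 36.8%, 87.9% and 90.9% of these changes between the WT groups, and 29.4%, 84.8% and 93.9% between TMS174 and WT, with 9 false calls in each. Far more design IDs were called in the data (5488 and 1392), which makes the adjusted threshold less strict there. The simulated shares are therefore not the recovery of the real comparisons. The slide number in the file headers placed the 6 WT arrays on slide 1 and both TMS174 arrays on slide 2.

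The alternatives fixed beforehand were quantile normalization, median scaling, no filter and a stricter filter (probes above background on all 8 arrays), the deposited ratio table, single probes, only the 2 groups compared, the replicate number as a block, a trended and robust spread, array weights, and leaving out each array. The planned normexp correction could not be run as written, since no mean spot signal was used here; it was run on median signals with an offset of 50. That version and scaling to 6 spike-in probes were chosen after seeing the data. Array number groups in the design IDs were compared with 10000 random lists of the same size matched on mean signal.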

Results

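Transcript abundance was measured on one-colour oligonucleotide arrays in Candida utilis (listed as Williopsis jadinii), an industrial yeast, to ask how its gene expression differs when xylose, a pentose sugar, replaces glucose and how a recombinant strain that ferments xylose differs from the wild type. The 8 arrays fall into 3 groups. Wild-type strain NBRC0988 (WT) was sampled after 10.5 h on glucose (n = 3) and after 24 h on xylose (n = 3), and strain TMS174, described by the labels as fermenting xylose, was sampled after 24 h on xylose (n = 2). Cultures were started at an OD600 of 0.1 in 50 ml of rich medium and grown semi-aerobically at 30 °C. The series description gives the replicates as independent experiments. Each array held 15208 yeast probes for 8604 design identifiers (design IDs), of which 7966 were tested. No design ID could be paired with a gene symbol here, so the results are given for the yeast's transcripts as sets, with design IDs named by a fixed rule. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.11 between the WT groups and 0.13 between TMS174 and WT on xylose. Between 87.8% and 95.2% of the probes were well above background on each array, and no probe was saturated.

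Correlations between arrays were higher within each group than between groups, by a small margin for the 2 xylose groups. Signals of replicate arrays correlated with Pearson's r (across design IDs, which are not independent replicates) of 0.990 to 0.995 for WT on glucose, 0.993 to 0.996 for WT on xylose and 0.996 for TMS174. WT arrays on xylose correlated with WT arrays on glucose at 0.926 to 0.944, whereas they correlated with the TMS174 arrays at 0.980 to 0.987. The TMS174 arrays correlated with WT on glucose at 0.948 to 0.956. The first principal component held 73.6% of the variance and ran from WT on glucose (-61.4 to -56.2) through TMS174 (24.1 and 24.4) to WT on xylose (39.9 to 47.6). The second held 14.9% and set TMS174 (-34.3 and -32.2) apart from WT on xylose (9.45 to 22.9) and on glucose (-5.37 to 10.0). TMS174 alone lay on the second slide, so strain and slide cannot be told apart there.

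The first comparison asked which transcripts of the wild type differed between 24 h on xylose and 10.5 h on glucose. More than 2 in 3 of the measured transcripts differed: 5488 of 7966 design IDs (68.9%), of which 2752 were higher and 2736 lower on xylose. At least 2-fold changes were found for 2085 design IDs, 1148 of them higher and 937 lower, and at least 4-fold changes for 537, 344 of them higher and 193 lower. The median change among the called design IDs was 1.74-fold.

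The 2 probes with the largest rise on xylose in WT belonged to 1 design ID, cut01g0060195. Its transcript was not well above background on any glucose array and reached 3.71 ± 0.13 (SD, n = 3) on the log2 scale relative to the array's 75th percentile on xylose, which is at least 5422-fold higher (limma, adjusted p = 3.6e-07). The 2 probes with the largest fall belonged to cut01g0030252 and cut01g0030251, which carry consecutive numbers. The level of cut01g0030251 was 2.64 ± 0.10 (SD, n = 3) on glucose and -5.50 ± 0.21 (SD, n = 3) on xylose, a log2 change of -8.13 (SE 0.12, limma adjusted p = 2.8e-07), or 281-fold lower. That of cut01g0030252 was -0.52 ± 0.21 on glucose and -8.85 ± 0.40 on xylose (SD, n = 3 each), at least 305-fold lower (limma adjusted p = 1.4e-06), with only 1 of the 3 xylose arrays well above background. Each "at least" value sets the brighter group's mean against that of the dim group. On each array of the dim group it takes the higher of the dim signal and the lowest signal well above background. The value holds under the main processing only and takes no account of the error of the means. Under normexp the log2 change was 9.35 for cut01g0060195 and -5.28 for cut01g0030252.

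**Figure D1:**
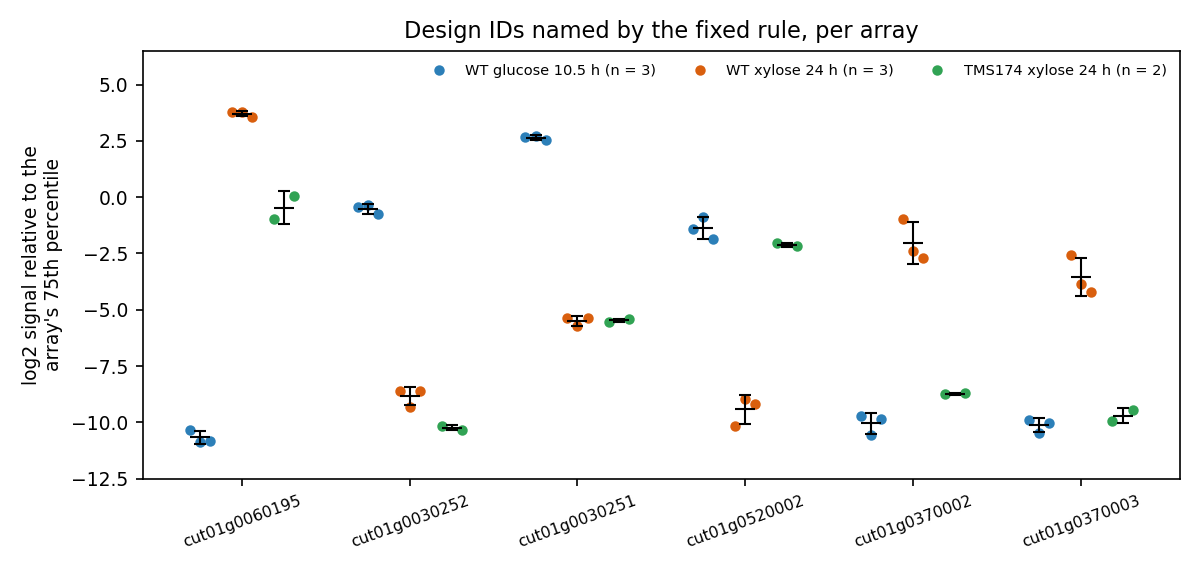
Log2 signal relative to each array's 75th percentile (vertical axis) for the 6 design IDs named by the rule (horizontal axis), in WT on glucose (n = 3), WT on xylose (n = 3) and TMS174 on xylose (n = 2). Points are arrays and black bars the mean ± SD. The design ID cut01g0520002 lies at -9.43 in WT on xylose and at -2.11 in TMS174, and cut01g0370002 and cut01g0370003 lie far higher in WT on xylose than in the other groups.

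Transcripts that were well above background in only 1 of the WT groups were mostly those of xylose. A set of 191 design IDs was above background on all xylose arrays and on no glucose array, against 15 with the opposite pattern. A small signal added to every probe of the WT xylose arrays could raise the count of 191, and this was not tested. The 1521 dimmest probes were also brighter as a set on the WT xylose arrays, at -9.16 ± 0.32 (SD, n = 3) against -10.4 ± 0.09 (SD, n = 3) on glucose (log2, relative to the 75th percentile). Of these probes, 79.1% had a higher mean on xylose. Before background subtraction their median intensities were 37 to 38.5 on xylose and 33 to 35.5 on glucose, over a local background of 24.5 to 27. Among the 1810 changes of at least 2-fold measured on both sides, 893 were higher and 917 lower.

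These calls come from limma with Benjamini-Hochberg adjustment at 0.05 over all 8 arrays; at an unadjusted p under 0.05 there were 5733. Medium and sampling time differ together here, and both groups lay on 1 slide. The balance of rises and falls depended on the scaling: scaling to the spike-in control spots moved the median of all design IDs to 0.42 (log2) and gave 3690 higher and 1142 lower (1949 and 494 at 2-fold), and normexp background correction moved it to -0.16 and gave 2172 higher and 3510 lower (601 and 672 of 1273 at 2-fold).

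**Figure D2:**
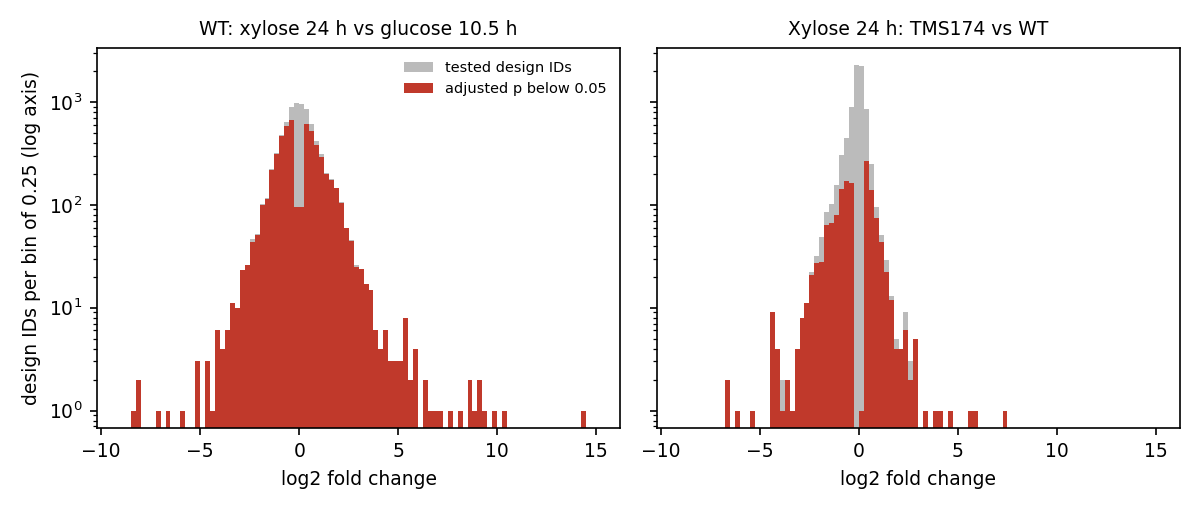
Histograms of the log2 fold change (horizontal axis) of the 7966 tested design IDs, as design IDs per bin of 0.25 on a log axis (vertical axis), for WT on xylose against WT on glucose (left) and TMS174 against WT on xylose (right). Grey bars are all tested design IDs and red bars those called; 5488 were called on the left and 1392 on the right.

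The second comparison asked which transcripts differed between TMS174 and the wild type when both were sampled after 24 h on xylose. Fewer transcripts were called than between the media: 1392 of 7966 design IDs (17.5%), 589 higher and 803 lower in TMS174, although the number of arrays differed too. At least 2-fold changes were found for 433 design IDs, 105 higher and 328 lower, and at least 4-fold changes for 116, 24 higher and 92 lower. The SD of the log2 changes over all design IDs was 0.61, against 1.15 between the media in WT.

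The 2 probes with the largest rise in TMS174 belonged to cut01g0520002. Its level was -2.11 ± 0.09 (SD, n = 2) in TMS174 and -9.43 ± 0.65 (SD, n = 3) in WT on xylose, where 2 of the 3 arrays were well above background, so that it was at least 114-fold higher in TMS174 (limma adjusted p = 0.00024). In WT the same transcript was at -1.38 ± 0.49 (SD, n = 3) on glucose and at least 188-fold lower on xylose (limma adjusted p = 7.0e-06). The 2 probes with the largest fall belonged to cut01g0370002 and cut01g0370003, again consecutive numbers. Both were well above background on every WT xylose array, at -2.03 ± 0.92 and -3.55 ± 0.86 (SD, n = 3 each), and on no WT glucose array. In TMS174, 3 of 4 and 2 of 4 of their spots were well above background. They were 105-fold (the fitted fold, which the bound did not change) and at least 47.7-fold lower than in WT on xylose (limma adjusted p = 0.00079 for each). These folds hold under the main processing only. Under normexp the log2 changes between the strains were 3.97 for cut01g0520002, -3.58 for cut01g0370002 and -2.36 for cut01g0370003. The transcript most strongly raised on xylose in WT, cut01g0060195, was 18.1-fold lower in TMS174 than in WT on xylose (log2 change -4.18, SE 0.30, limma adjusted p = 0.00071), and was still at least 300.1-fold higher there than in WT on glucose. The log2 change of cut01g0030251 between the strains was 0.02 (SE 0.13, limma adjusted p = 0.94).

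Of the 433 changes of at least 2-fold, 134 involved a transcript that was not well above background in 1 of the strains, and 132 of these were lower in TMS174. The 299 others, above background on at least 1 array of each strain, comprised 103 higher and 196 lower. The 1521 dimmest probes stood at -10.4 in TMS174 (both arrays, n = 2), 1.24 below its mean on the WT xylose arrays. Near the background this is a small difference in intensity: before subtraction their medians were 36 and 35 in TMS174 and 37 to 38.5 in WT on xylose.

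The calls rest on the same limma fit; at an unadjusted p under 0.05 there were 2690. The TMS174 arrays lay on a slide of their own, so strain and slide cannot be told apart. The count depended on single arrays, being 614 without WT xylose replicate 1, 553 without WT xylose replicate 3, 360 without TMS174 replicate 1 and 317 without TMS174 replicate 2, and the 2-fold count fell to 252, 244 and 234 without the last 3 of these. Array weights gave 2723 calls, and the replicate number as a block gave 744 (315 at 2-fold). The balance of directions depended on the scaling: quantile normalization gave 719 higher and 530 lower calls (155 and 165 at 2-fold), median scaling 795 and 678, normexp 698 and 520 (68 and 99), and spike-in scaling, which moved the median of all design IDs to -0.59, gave 83 and 4329 (43 and 1375). With only probes above background on all arrays, which also leaves out transcripts that fell to background, 645 were higher and 652 lower (107 and 148 at 2-fold), and without TMS174 replicate 1 the 2-fold calls were 93 higher and 151 lower.

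The last question the 3 groups allow is where TMS174 on xylose stood relative to both WT conditions. Under the main scaling, transcripts that changed on xylose in WT tended to change in the opposite direction in TMS174 relative to WT on xylose. Of the design IDs higher on xylose in WT, 423 were lower and 100 higher in TMS174, where lists with no relation would share 277 and 203. Of those lower on xylose in WT, 372 were higher and 197 lower in TMS174, against 202 and 276. Spike-in scaling, under which nearly all calls in TMS174 were lower, moved the counts: 2313 of those higher on xylose were lower and 5 higher in TMS174 (2005 and 38.4 for lists with no relation), and of those lower on xylose 427 were lower and 55 higher (621 and 11.9). Opposite calls thus exceeded those of lists with no relation under that scaling too, although most of the shared calls lower on xylose were also lower in TMS174. A further 117 design IDs were higher and 183 lower in TMS174 with no call between the media in WT.

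Both comparisons use the WT xylose arrays, with opposite sign, which by itself gives a negative relation. Across design IDs, which are not independent replicates, the 2 sets of log2 fold changes had a Pearson's r of -0.46 and a Spearman's rho of -0.32, and 100 simulated sets of unchanged groups sharing those arrays gave a mean r of -0.45 (range -0.49 to -0.39) and a mean rho of -0.41 (range -0.43 to -0.38). In such sets r follows from the group sizes. Its likeness to the observed r therefore does not show that the shared arrays explain the relation. The covariance, which depends on the size of the changes, was -0.324, against -0.0191 (range -0.0221 to -0.0162) in the simulations, a difference of -0.305. Independent noise of the shared arrays thus made up a small part of the covariance. The simulated groups held no changes, so this comparison sizes the noise alone. True levels of WT on xylose also enter both changes with opposite sign. The rest of the covariance therefore does not by itself show a move of TMS174 towards WT on glucose. The covariance was -0.154 under normexp and -0.204 with only probes above background on all arrays. A shift common to all WT xylose arrays was not simulated. With 3 WT xylose arrays the shared arrays could not be divided into sets of at least 2, so part of the excess of shared calls over lists with no relation may come from them.

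Among the 1148 design IDs at least 2-fold higher on xylose in WT, 859 (74.8%) had a mean in TMS174 between the WT means on glucose and xylose. The median TMS174 change from WT on glucose was 80.9% of the WT change on the log2 scale (quartiles 47.5% and 97.0%). Among the 937 lower ones, 568 (60.6%) lay between, with a median of 91.1% (quartiles 70.5% and 113%). Simulated TMS174 arrays with the WT xylose means gave 49.9% to 56.3% between for the higher set and 48.8% to 59.2% for the lower set, with mean medians of 99.0% and 98.9%. These simulations vary each design ID by itself and hold no shift shared by an array or slide. Their ranges are therefore too narrow to judge the observed shares by. For 889 higher and 887 lower design IDs above background in every group the shares were 73.5% and 62.7%. Their medians were 87.5% and 90.3%, so part of the shortfall of the higher set came with dim design IDs. Over all tested design IDs, the medians of the higher and lower sets were 88.0% and 83.4% under quantile normalization. Median scaling gave 83.4% and 86.8%, and normexp 89.5% and 87.2%. Spike-in scaling gave 87.2% and 25.9%, with medians of 49.7% of the WT change for the higher set and 124% for the lower set, so that the lower set then mostly lay past WT on xylose.

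**Figure D3:**
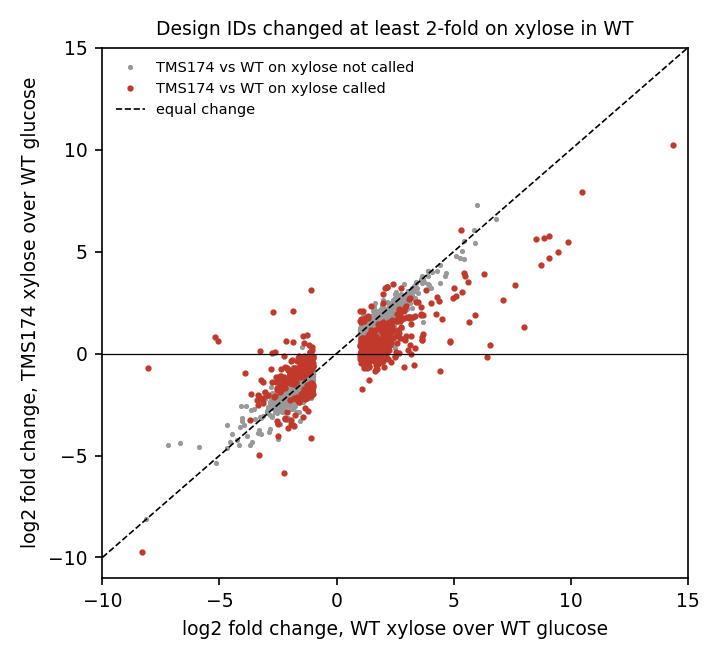
Log2 fold change of TMS174 on xylose over WT on glucose (vertical axis) against that of WT on xylose over WT on glucose (horizontal axis) for the 2085 design IDs changed at least 2-fold in the latter. Each point is a design ID, in red where TMS174 differed from WT on xylose, and the dashed line marks equal change; 859 of the 1148 on the right lie between the horizontal zero line and the dashed line.

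Compared directly with WT on glucose, from which it differs in strain, medium, time and slide, TMS174 on xylose differed in 5017 design IDs (limma, adjusted p under 0.05), 2358 of them higher and 2659 lower, with 1878 changed at least 2-fold (852 higher and 1026 lower). Spike-in scaling, which moved the median of all design IDs to -0.19, gave 1251 higher and 2435 lower (686 and 1327 at 2-fold), and normexp moved that median to -0.14 and gave 1152 changes of at least 2-fold. The transcript cut01g0520002 was lower there by a log2 change of -0.73 (SE 0.40, limma adjusted p = 0.15), which did not pass the test. For cut01g0370002 and cut01g0370003 no fold is given, since no WT glucose array was well above background and the TMS174 signals lay near it.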

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

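The tests of array scaling, of WT xylose replicate 3 and of an added signal were chosen after the result was seen. The spike-in control spots enter no main comparison and hold a signal of their own: relative to them, the 75th percentile of the yeast probes was higher on WT xylose arrays than on WT glucose arrays by 0.406 on the log2 scale (1.96 ± 0.23 against 1.56 ± 0.13, SD, n = 3 each; exact permutation test, two-sided, p = 0.1, the smallest this design allows). Whether equal amounts of the spike-in were added is not given in the sources used here. In TMS174 it was 1.41 ± 0.08 (SD, n = 2). No group has the 4 arrays that a test for single outlying arrays needs.

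Changes of at least 2-fold between TMS174 and WT on xylose were mostly lower in TMS174 (328 of 433), and 132 of these had a side not well above background; the share of higher calls was 24.2%, and 42.0% with only probes above background on all arrays, a filter that itself leaves out transcripts that fell to background. A higher nonspecific signal on the WT xylose arrays is argued against only as far as negative-control spots can show it. They were 0.13 higher there than on the TMS174 arrays (log2, summed SDs 0.36), while the 1521 dimmest probes were 1.24 higher. Both lie near the background, where log2 values magnify small differences. Before background subtraction, the median intensity of the dimmest probes was 37 to 38.5 on WT xylose arrays and 36 and 35 on TMS174 arrays. Negative controls stood at 28.5 to 29 and at 31 and 30, and the local background at 25 to 27. WT xylose replicate 3 as the only source is argued against, because 36.1% of the 2-fold calls were higher without it, still a minority. The imbalance shrank, though: without that array 91 were higher and 161 lower, against 105 and 328 with it. A small signal added to every probe of the WT xylose arrays, as carried-over genomic DNA could give, stays untested: 94.3% of the 1521 dimmest probes were brighter there, but this restates their known shift, and a broad rise of rare transcripts would look alike, so both stay open, as do strain and slide. Array scaling cannot be told apart either: quantile normalization, which makes the dim ends of all arrays equal, gave 48.4% higher, but median scaling gave 29.5%.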

How the results depend on the processing

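The tests of splits, the spike-in scaling and normexp were chosen after the results were seen. The named design IDs kept their direction and their side of the threshold in all 94 values obtained under alternatives on design IDs. These design IDs had been picked as the largest changes on the same arrays, so this was likely beforehand and does not bear on other design IDs. Their sizes moved, most under normexp, as given above. With only probes above background on all arrays, 1 of the 6 (cut01g0030251) had a value. Between the WT media, the count of 5488 stayed within 1.5 times under each alternative on design IDs. It was 4973 to 5694 when 1 array was left out. The 2-fold count of 2085 moved by more than 1.5 times only under normexp (1273). That count was 2443 under spike-in scaling, 1655 with only probes above background on all arrays, and 1965 to 2172 with 1 array left out. All 10 splits of the 6 WT arrays are too few for a share under 0.05. The real split (1 of the 10) called 5488 and the highest other 0, and the same held at 2-fold (1 of 10, 2085 against 0). Every other split puts arrays of both media in both groups, so the media difference adds to the spread within them. The 0 calls there therefore do not show what splits of like arrays would give. Testing each probe by itself gave 9607 and 3551 probes of 14195 between the WT media, and 8784 and 3282 between TMS174 and WT on glucose, since more features were tested. Between TMS174 and WT on xylose the count of 1392 became 4412 under spike-in scaling (1418 at 2-fold), 2723 with array weights and 744 with the replicate block, and the 2-fold count of 433 became 167 under normexp and 255 with probes above background on all arrays, for which fewer were tested; leaving out 1 array gave 317 to 1134 calls, and 234 to 460 at 2-fold. With the filter on all arrays, 7200 design IDs were tested rather than 7966, and transcripts that fell to background were left out too. The part of each in the lower count was not separated. The cause was not tested for any of these settings. Between TMS174 and WT on glucose normexp gave 1152 at 2-fold, and leaving out 1 array gave 3848 to 5340 calls and 1749 to 2049 at 2-fold. The correlation between the 2 sets of changes, -0.46, was -0.50 under quantile normalization, -0.40 with probes above background on all arrays, -0.49 with the replicate block, and -0.48 to -0.43 with 1 array left out. Whether the replicate numbers pair the arrays cannot be told from so few arrays. Deviations of same-numbered arrays of the WT groups correlated at 0.03, 0.18 and 0.08, and those of arrays with different numbers at -0.21 to 0.12. Of the 6 WT arrays, 4 matched their own number best. The block gave 5380 calls between the WT media. In the fits without TMS174 replicate 1 or 2 the lone array is assumed to vary like the other groups. The slide could not be fitted as a block, since TMS174 alone lay on the second slide, and the gene list tests were not run, as no design ID has a symbol here. Dim probes limit the rest: 275 of the 2085 and 134 of the 433 changes of at least 2-fold had a side not above background. Of the 275 between the WT media, 255 were higher on xylose.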

Other observations

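All tests in this part were chosen after the data or the results were seen. The design IDs consist of a 3-digit group number and a 4-digit serial number; what the groups stand for is not given in the sources used here. Of 13 number groups with at least 10 tested design IDs, compared in both main comparisons (26 tests), only cut01g008 passed after adjustment. Of its 20 tested design IDs, 17 were lower and 1 higher on xylose than on glucose in WT, with a median log2 change of -1.51. In TMS174, 16 were higher and none lower than in WT on xylose, with a median of 0.96. Both changes use the WT xylose arrays, with opposite sign, so the fall and the rise are not independent results. The array medians of the group were -3.74 to -3.59 in WT on glucose, -5.36 to -5.19 in WT on xylose, and -4.44 and -4.24 in TMS174, so the 3 groups did not overlap. Each median lay outside all 10000 random lists matched on mean signal (permutation p = 2e-04, the smallest they can give, adjusted p = 0.0026), as a description of these arrays. The random lists drew design IDs singly, whereas changes of consecutive numbers were correlated, as given below. Their ranges may therefore be too narrow for a number group. In cut01g011, 8 of 14 design IDs were lower and 2 higher on xylose in WT (median -0.74, permutation p = 0.0058, adjusted p = 0.0503), and its median between the strains was 0.15 (permutation p = 0.013, adjusted p = 0.0845); neither passed.

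The shared shift of cut01g008 was singled out after its values were seen, so that its members respond together is a hypothesis. For the fall in WT, array scaling is argued against, since the median stayed at -1.10 or lower under quantile, median and spike-in scaling, and dim probes are argued against, since 1 of the 20 design IDs was not above background on WT xylose and the other 19 had a median of -1.50. The slide is excluded there, because 1 slide held both groups. Medium and time stay open. For the rise in TMS174, whose median was 0.41 to 1.06 under those scalings, strain and slide cannot be told apart, since the 2 strains lie on 2 slides.

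Log2 changes of design IDs with consecutive numbers were correlated, with a Spearman's rho of 0.21 between the WT media and 0.18 between the strains over 7128 pairs (p = 1e-04 for each, the smallest 10000 permutations can give), and at a distance of 5 numbers it was 9.2e-05 and 0.019. Position on the array is argued against, since neighbours far apart on it correlated at 0.227 and 0.203 and near ones at 0.188 and 0.149, and so are dim probes as the whole cause, since pairs brighter than the median design ID kept 0.120 and 0.086, above the highest of 1000 permuted values (0.077 and 0.065). Shared noise made up 1.99% of the neighbours' covariance between the WT media, which argues against it there, and 11.9% between the strains, which leaves it open as a part. Neighbouring genes under common control, overlapping transcripts or 1 gene split over 2 design IDs may all give such pairs, and no sequence or coordinate was used here that would separate them.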
